A study of Ixodes scapularis with 9 samples.

How the data were processed

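The libraries were made from salivary glands of unfed and partially fed adult female ticks, dissociated mechanically and enzymatically, with polyA selection and a directional kit and paired-end sequencing on an Illumina instrument, per the labels' protocols. Per the series text, the authors trimmed reads with Cutadapt, aligned them to assembly ASM1692078v2 with STAR in 2-pass mode and quantified genes with RSEM within a published workflow. FastQC, cutadapt, STAR and RSEM are also named in the submitters' processing notes. Tool versions, the annotation release and the strand setting are not given in the sources used here. The authors deposited expected counts per gene, in which RSEM splits reads that fit several genes between them, so genes with near-identical copies are less certain. The authors also deposited TPM, which are scaled to gene length and to a sum of 1000000 per library, and FPKM, which are scaled to gene length and assigned fragments. FPKM served only to derive the effective length of each gene from the deposited tables. Of all 32436 entries per library, 6.87 to 11.57% had an expected count that was not whole (tolerance 0.005). Entries at 0 are whole and are part of that base, and only 12705 to 14855 genes per library had a count. The share among genes with a count is thus higher. Of the 12080 tested genes, 7311 were whole in all 9 libraries.

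Each table held 32436 gene entries. All 29689 LOC entries were matched by symbol to an NCBI RefSeq gene table of the same assembly, giving 26659 protein-coding, 2322 lncRNA, 442 rRNA, 120 snRNA, 110 misc_RNA, 19 snoRNA genes and 17 transcribed pseudogenes. The 2747 tRNA entries had no count in any library. The RefSeq table gives no product names, so the 36 gene lists, the secreted family shares and the family counts planned before the data were examined were not analysed here, and no gene function is stated. The table also names no chromosome. Neighbouring genes were taken from its order, and a fall of the start position was read as a new sequence, which gave 356 sequences; a new sequence that begins at a higher position is missed by this rule.

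Groups came from the library titles and descriptions. Expected counts were rounded to whole numbers and analysed in edgeR 4.0.16 under R 4.3.3. Genes were kept with filterByExpr (minimum count 10), leaving 12080, scaled with TMM, and fitted in 1 model over all 9 libraries with 1 mean per group and robust quasi-likelihood dispersions (glmQLFit, glmQLFTest). All libraries shared 1 estimate of the spread, with a common biological coefficient of variation of 0.38. Tests were made for G2 vs UF, G5 vs UF, G5 vs G2 and over all 3 groups, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM are TMM-normalised. The SE of a log2 fold change was its size over the square root of the F statistic. Printed fold changes of genes with no count in a group were replaced by bounds against 3 counts over that group. With 1 to 3 counts they were replaced by a ratio with a 95% counting interval. Counts of genes by fold change, runs, correlations, the covariance and the plot of fold changes used the values as fitted. These bounds and intervals cover counting error only. Shares were compared by exact permutation of 3 against 3 libraries, which cannot go below 0.1, and biotypes by Fisher's exact test.

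Totals of 11246475 to 13788073 expected counts per library set the precision. In simulated counts with 200 changed genes, the G2 vs UF test recovered 26.8% of 2-fold and 59.8% of 4-fold changes, the G5 vs UF test 30.9% and 61.1%, and the G5 vs G2 test 29.5% and 56.2%. Of the genes called there, 11.6%, 11.2% and 6.8% were unchanged, above the nominal 5%. No libraries were duplicates: chi-square per gene between replicates was 16 to 65.6. Chance values from the shared UF libraries came from 50 simulated sets of unchanged groups.

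The genes named were fixed by a rule before the data were examined: in each comparison the 8 largest rises and 8 largest falls among called genes with at least 50 CPM in the higher group and all 3 of its libraries above all 3 of the other, and the 5 most abundant genes of each group. The abundant genes are all given, and of the largest rises and falls the first few are given in full and the rest as ranges of their levels. The rule asked for informative product names where these exist. Alternatives were RLE and upper-quartile scaling, scaling without the 100 most abundant genes, no filter, at least 10 CPM in 3 libraries, DESeq2 1.42.0, limma-trend (limma 3.58.1) on log2(TPM + 1), fits of only the groups compared, thinning to the shallowest library, a replicate block and leaving out each library. Chosen after the data were seen were limma-voom with quality weights per group, only genes with whole expected counts, and the lncRNA share as TPM or without LOC8036515. Figures were drawn with matplotlib 3.10.9.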

Results

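RNA was sequenced from dissociated salivary glands of adult female Ixodes scapularis, the blacklegged tick, an obligate blood feeder that stays attached to its host for days and secretes saliva into the bite. Glands were pooled into 9 libraries, 3 in each of 3 groups. The unfed group (UF) had 15 females per pool, with a mean tick weight of 1.6 mg. The partially fed group G2 had 5 females per pool, with a mean weight of 7.4 mg in the library descriptions and 7.2 mg in the series text. The heavier partially fed group G5 had 4 females per pool, with a mean weight of 44.5 mg in the library descriptions and 41.5 mg in the series text. The fed ticks came from 4 rabbits, and the labels do not tie pools to rabbits. The p-values of expression tests and of shares of counts therefore measure the spread between pools. Fisher's exact tests of biotypes and permutations of gene length take genes as units, so their p-values do not measure that spread. The number of females per pool fell as tick weight rose, so pool size and feeding group changed together in every comparison. Total expected counts per library were 12296025 to 13788073 in UF, 11246475 to 13155353 in G2 and 11398863 to 12209895 in G5. Genes are given by the LOC symbols of the count tables, because the annotation table used here pairs these symbols with a biotype and a position but with no product name. Positions are on assembly ASM1692078v2, and that table does not name the sequence a position belongs to.

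The libraries separated by group. Spearman correlations across the 12080 tested genes were 0.978 to 0.983 between UF libraries, 0.957 to 0.968 between G2 libraries and 0.956 to 0.961 between G5 libraries. They were 0.902 to 0.922 between G2 and G5, 0.81 to 0.855 between UF and G2, and 0.793 to 0.806 between UF and G5. The first principal component, with 57.4% of the variance, placed the UF libraries at -136.2 to -133.8, the G2 libraries at 38.9 to 65 and the G5 libraries at 81.1 to 83.9. In the test over all 3 groups, 7360 genes (60.9%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test.

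Of the 10 genes among the 5 most abundant of any group, 9 passed the G2 vs UF test and all 10 the G5 vs UF test, with changes of very different size. LOC8036515, annotated as a long non-coding RNA gene (69971598 to 69981666), was the most abundant gene in unfed glands at 40600 ± 502 CPM, counts scaled to a library total of 1000000 (SD, n = 3). It was 9.45-fold lower in G2 at 4300 ± 1280 CPM (log2 fold change -3.24, SE 0.24, edgeR adjusted p = 1e-06) and 4.23-fold lower in G5 at 9590 ± 2340 CPM (log2 fold change -2.08, SE 0.23, edgeR adjusted p = 1.15e-05). Its level was 2.23-fold higher in G5 than in G2 (edgeR adjusted p = 0.00326). The protein-coding gene LOC8041558 (start 102051272) went from 22500 ± 1670 CPM in UF to 2050 ± 375 in G2 and 1190 ± 90.6 in G5, falling in each step (edgeR adjusted p = 9.13e-08 for G2 vs UF and 0.004 for G5 vs G2). LOC8026786 went from 10100 ± 650 CPM in UF to 999 ± 190 in G2 and 744 ± 44 in G5. Both differences of LOC8026786 from UF passed the test, and its G5 vs G2 difference did not (edgeR adjusted p = 0.0635, 0.0196 to 0.169 over the alternatives). LOC8026527 (76405492 to 76529660) was the most abundant gene of both fed groups, at 5070 ± 554 CPM in UF, 22000 ± 3880 in G2 and 30100 ± 2750 in G5. It was 4.33-fold higher in G2 than in UF (log2 fold change 2.12, SE 0.16, edgeR adjusted p = 1.62e-06) and 5.93-fold higher in G5 than in UF (log2 fold change 2.57, SE 0.17, edgeR adjusted p = 3.03e-07). Between G5 and G2 its difference did not pass the test (edgeR adjusted p = 0.0589). That p was 0.0222 to 0.144 over the alternatives, passing with DESeq2, in limma-voom and without G2 replicate 1 (adjusted p = 0.0222, 0.0436 and 0.0417). LOC8027393 rose in both steps, from 1660 ± 73.8 CPM in UF to 4460 ± 330 in G2 and 9430 ± 772 in G5. LOC115309571 did so as well, from 2510 ± 246 to 5420 ± 1060 and 8510 ± 888 CPM. LOC8028296 was at 1900 ± 291 CPM in UF, 7100 ± 1450 in G2 and 6390 ± 1350 in G5, higher in both fed groups than in UF but with no call between them (edgeR adjusted p = 0.638). LOC8035179 fell in both steps, from 11000 ± 116 to 6050 ± 439 and 3960 ± 278 CPM (edgeR adjusted p = 0.000108 and 0.00394). LOC8035905 was at 13000 ± 926 CPM in UF, 6550 ± 1280 in G2 and 8180 ± 1050 in G5, lower in both fed groups than in UF, with a G5 vs G2 edgeR adjusted p of 0.184 (0.0431 to 0.411 over the alternatives, passing without G2 replicate 3). LOC8035131, the second most abundant gene of both fed groups, was at 6980 ± 1240 CPM in UF, 8330 ± 2340 in G2 and 12600 ± 921 in G5. It was called in G5 vs UF (edgeR adjusted p = 0.00463) and not in G2 vs UF (edgeR adjusted p = 0.33, and 0.0256 without G2 replicate 2, in a range of 0.0256 to 0.691) or G5 vs G2 (edgeR adjusted p = 0.0598, and 0.027 with DESeq2 and 0.0432 without G2 replicate 3, in a range of 0.027 to 0.145). RSEM had split reads of all of these genes with other genes in at least 1 library, so part of each level may belong to a similar sequence. The 10 most abundant genes of each library held 12.6% ± 0.383 of counts in UF, 8.19% ± 0.866 in G2 and 9.95% ± 0.53 in G5 (SD, n = 3). With shares of TPM in place of counts, the G5 value (12.6% ± 0.975) lay above that of UF (9.37% ± 0.102). Each pair of groups was fully separated in both units, with an exact permutation p of 0.1 (two-sided), the smallest that 3 against 3 libraries allow.

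**Figure D1:**
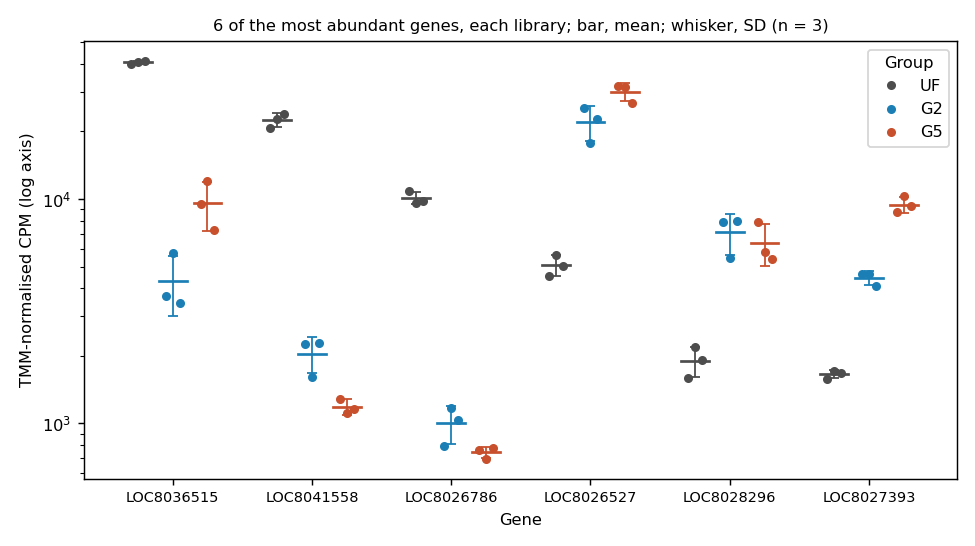
TMM-normalised CPM on a log axis for 6 of the most abundant genes in each library of UF, G2 and G5, with bars for group means and whiskers for the SD (n = 3). LOC8036515, LOC8041558 and LOC8026786 have their highest values in UF, with means of 40600, 22500 and 10100 CPM, and LOC8026527, LOC8028296 and LOC8027393 have their lowest values there.

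The comparison of G2 with UF asks how the gland transcriptome of lightly fed ticks differs from that of unfed ones. Many genes went from no detectable reads to moderate levels. LOC120843411 (118064071 to 118089383) had no count in UF and 436 ± 101 CPM in G2 (n = 3), at least 5590-fold higher against a floor of 3 counts over the UF group (edgeR adjusted p = 4.21e-08). LOC120838229 (2797083 to 2842712) had no count in UF and 643 ± 192 CPM in G2, at least 8250-fold higher (edgeR adjusted p = 0.00901). That call was lost in limma-voom with a spread estimated per group (adjusted p = 0.0894, range over all alternatives 8.64e-16 to 0.0894). In the other direction, LOC120841911 (309919 to 331549) had 142 ± 10.4 CPM in UF and no count in G2, at least 1850-fold lower (edgeR adjusted p = 2.4e-06). LOC120841921 (88684165 to 88705883) had 242 ± 66.1 CPM in UF and 1 count in all of G2, a ratio of 9520 with a 95% counting interval of 1710 to 376000 (edgeR adjusted p = 9.13e-08). Of the 8 largest rises taken by the naming rule, all 8 had no count in UF, with G2 levels of 148 to 643 CPM. Of the 8 largest falls, 1 had no count in G2 and 4 had 1 to 3 counts there, from UF levels of 58.9 to 242 CPM. All 16 are annotated as protein-coding. Across the transcriptome, 6056 of 12080 genes (50.1%) passed the test, 3173 higher and 2883 lower in G2. With upper-quartile scaling the balance turned to 2973 higher and 3166 lower. At least a 2-fold change was seen in 2291 higher and 1881 lower genes, and at least 8-fold in 717 higher and 406 lower genes. Among the 7311 genes whose expected counts were whole in all 9 libraries, a smaller set with no read split between genes, 3845 passed.

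The comparison of G5 with UF asks the same of more heavily fed ticks. LOC115328396 (103730864 to 103734858) had no count in UF and 2040 ± 468 CPM in G5 (n = 3), at least 26100-fold higher (edgeR adjusted p = 7.52e-06), and was at 23.2 ± 14.3 CPM in G2 (15.4 without G2 replicate 3). LOC115314729 (101859620 to 101871030) had no count in UF, 203 ± 77.1 CPM in G2 and 3090 ± 2010 in G5, at least 39700-fold higher in G5 than in UF (edgeR adjusted p = 3.37e-05). Without G5 replicate 2 its G5 mean was 1950 CPM, at least 25000-fold higher. LOC120843586 had 1 count in all of UF, 462 ± 92.9 CPM in G2 and 4650 ± 936 in G5 (edgeR adjusted p = 1.7e-09 for G5 vs UF). LOC120841921, at 242 ± 66.1 CPM in UF, had no count in G5, at least 2730-fold lower (edgeR adjusted p = 4.67e-08). LOC120841918 (709062 to 729506) had 185 ± 31 CPM in UF, 1.33 ± 1.09 in G2 (0.777 without G2 replicate 1) and no count in G5, at least 2080-fold lower in G5 than in UF (edgeR adjusted p = 1.18e-05). Of the 8 largest rises, 7 had no count in UF and 1 had 1 count, with G5 levels of 460 to 4650 CPM. Of the 8 largest falls, 7 had no count in G5. In total 6503 genes (53.8%) passed the test, 3513 higher and 2990 lower in G5. The split was nearly even with upper-quartile scaling (3299 higher, 3258 lower) and in limma-trend on log2(TPM + 1) (3364 higher, 3332 lower). At least a 2-fold change was seen in 2654 higher and 2154 lower genes, and at least 8-fold in 981 higher and 384 lower genes. Among the 7311 genes with whole expected counts, 4235 passed.

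Genes with no count in one group were counted as a class after the data had been seen. In all 3 UF libraries together, 92 genes with at least 10 CPM in G2 had no count, and 89 of these passed the G2 vs UF test. For G5 the number was 148, of which 142 passed the G5 vs UF test, and these 148 genes together held 1.71% of normalised G5 counts. Both fed groups shared 61 such genes. Only 4 genes with at least 10 CPM in UF had no count in G2, and 13 had no count in G5. A floor of 3 counts over the group puts each such difference at 113-fold or more.

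Several of the deepest falls came from neighbouring genes, a feature that was singled out after the values were seen. LOC120841911, LOC120841918, LOC120841904, LOC120841914 and LOC120841891 lie on 1 short stretch of the assembly from 87998 to 892200, read as 1 sequence because start positions rise without a break in the annotation table. A boundary to a sequence that begins at a higher position would be missed by that reading, so these genes may lie on more than 1 sequence. That stretch held 14 annotated and 11 tested genes. In both fed groups 8 of the 11 were at least 4-fold lower than in UF, and 6 of these 8 had no count in G5. The fallen genes ranged from LOC120843768, at 9.9 ± 2.47 CPM in UF with no count in G2 or G5 (edgeR adjusted p = 0.000145 for G5 vs UF), to LOC120841918. The other 3 genes, interspersed among them, rose in G2. LOC120841905 went from 0.484 ± 0.277 CPM in UF to 15.6 ± 1.79 in G2 (edgeR adjusted p = 0.000469) and was at 0.973 ± 1.09 in G5. LOC120841915 went from 4.14 ± 1.4 to 65.4 ± 1.44 CPM (edgeR adjusted p = 0.00271) and was at 7.52 ± 7.32 in G5. LOC120841912 went from 0.56 ± 0.382 CPM to 48.7 ± 54 (edgeR adjusted p = 0.00139) and was at 14.2 ± 6.81 in G5. Its G2 mean rested on G2 replicate 3 and was 17.9 CPM without it, and the G5 mean of LOC120841915 was 3.62 CPM without G5 replicate 1. Between G5 and G2 LOC120841912 was not called (edgeR adjusted p = 0.167). RSEM had split reads of the 3 risen genes with other genes in 8 of the 9 libraries, and reads of 7 of the 8 fallen genes in 3 to 5 libraries, so these levels are uncertain. LOC120843768 had whole counts in all 9. The fallen genes had at most 50 counts in all of G2 and 6 in all of G5, and a count of 0 is always whole. For them, 3 to 5 can thus be most or all of the libraries with reads.

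**Figure D2:**
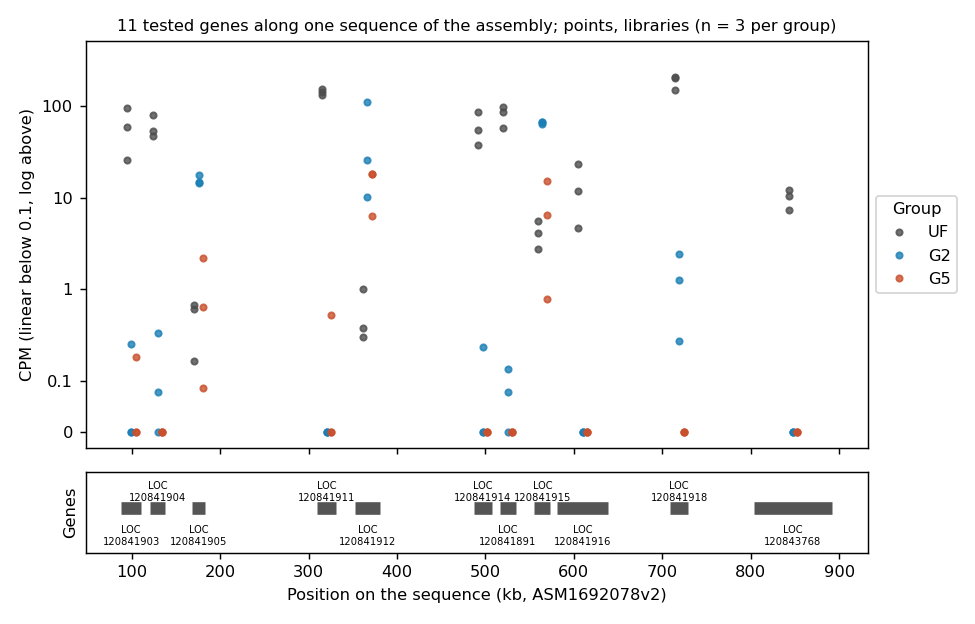
CPM of 11 neighbouring tested genes in each library (points, 3 per group; axis linear below 0.1 CPM and log above), placed at the midpoint of each gene on the sequence in kb, with gene spans drawn underneath. In 8 of the genes the UF points lie far above those of G2 and G5, and in LOC120841905 and LOC120841915 the G2 points lie highest, with means of 15.6 and 65.4 CPM. In LOC120841912 the G2 points (10.2, 25.5 and 110 CPM) overlap those of G5 (6.29 to 18.2 CPM).

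The comparison of G5 with G2 asks what changed between the lighter and heavier fed ticks. LOC8054029 (9101153 to 9170228) had no count in UF or G2 and 1100 ± 207 CPM in G5 (n = 3), at least 14300-fold higher in G5 than in G2 (edgeR adjusted p = 3.81e-06). LOC115309969 (77533879 to 77566286) had no count in UF or G2 and 390 ± 95.2 CPM in G5, at least 5090-fold higher (edgeR adjusted p = 8.53e-06). In all, 26 genes with at least 10 CPM in G5 had no count in UF or G2, against 1 gene with at least 10 CPM in G2 and no count in UF or G5. LOC8024467 (108297794 to 108306887) had 18 ± 7.02 CPM in UF, 81.6 ± 66.6 in G2 and 0.478 ± 0.225 in G5 (log2 fold change G5 vs G2 -7.39, SE 0.79, edgeR adjusted p = 0.000348), a call lost in limma-voom with a spread per group (adjusted p = 0.0923, the highest of all alternatives, the lowest being 1.34e-29). Its G2 mean was 44 CPM without G2 replicate 3. LOC8028693 (37336036 to 37352237) had 253 ± 362 CPM in G2 and 2 counts in G5, a ratio of 4730 with a 95% counting interval of 1310 to 39000 (edgeR adjusted p = 0.0127). Its SD exceeded its mean in G2, which was 44.3 CPM without G2 replicate 2, and its call was lost without G5 replicate 1 (adjusted p = 0.0523), without G5 replicate 2 (0.0853) and in limma-voom (0.456, with 3.1e-09 as the lowest of all alternatives). Of the 8 largest rises, 4 had no count in G2, with G5 levels of 66.7 to 1100 CPM, and the 8 largest falls had G2 levels of 52.1 to 253 CPM. In total 2829 genes (23.4%) passed the test, 1386 higher and 1443 lower in G5. At least a 2-fold change was seen in 839 higher and 558 lower genes, and at least 8-fold in 291 higher and 78 lower genes. On log2(TPM + 1) with limma-trend, which moved the median of all genes by -0.11, the split was 1130 higher and 1905 lower, and that of genes changed at least 2-fold was 760 higher and 764 lower. Among the 7311 genes with whole expected counts, 1843 passed. The main fit shared 1 estimate of the spread with UF, whose replicates spread less than those of either fed group. A fit of only G2 and G5 called 2154 genes, 2110 of them among the 2829. In limma-voom with a spread per group 2381 were called, 2279 of them among the 2829.

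Genes that differed from UF in both fed groups mostly did so in the same direction. Both fed groups were called higher than UF for 2574 genes and lower for 2114. Independent lists of these sizes would share 923 and 714 genes, and unchanged groups simulated against the same UF libraries shared 0.06 calls on average. Since almost no gene is called in such sets, that value does not bound what shared UF noise adds among changed genes. Fold changes against UF correlated across genes, which are not independent replicates, with r = 0.81, where simulation without any effect gave 0.503 because UF is shared. Their covariance was 5.23 against a simulated 0.279, a difference of 4.953. The correlation and covariance used fold changes as fitted, in which genes with no count in UF can have large values in both comparisons. In simulation each gene had its mean over all 9 libraries in every group, so no gene was set to be off in UF alone. What such genes add to the correlation and covariance was not tested. The simulated value already includes the shared UF libraries, with the spread estimated over all 9 libraries. With 3 UF libraries the controls could not be split into sets of at least 2 to check that value. A remaining part from the shared controls is therefore not ruled out. By the steps from UF to G2 and from G2 to G5, 4272 genes passed only the first test (2291 higher, 1981 lower) and 1045 only the second (582 higher, 463 lower). Both steps went the same way in 808 genes, 355 up and 453 down, as in LOC8027393 and LOC8041558. They went opposite ways in 976 genes, 527 up and then down and 449 down and then up. Simulated unchanged groups gave on average 0 genes with both steps called the same way and 0.02 with both called opposite ways. Almost no gene is called in such sets, so they do not give the chance level among genes that did change. The steps share the G2 libraries, whose noise enters them with opposite signs and favours opposite calls. Without G2 replicate 1 the total of 976 became 634. A gene that passed 1 test and not the other is not shown to differ between the steps.

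**Figure D3:**
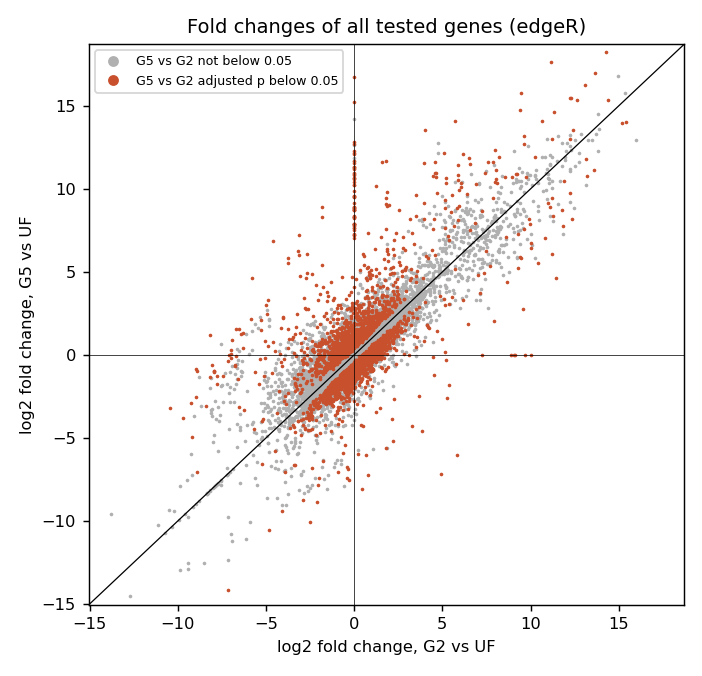
Each point is 1 of 12080 tested genes, with its edgeR log2 fold change G2 vs UF on the x axis and G5 vs UF on the y axis; the diagonal marks equal changes and orange points are the 2829 genes called between G5 and G2. Most points lie near the diagonal (r = 0.81 across genes, 0.503 in simulated unchanged groups that share the UF libraries). Genes with no count in a group are drawn at their fitted fold change.

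By biotype, called lncRNA genes leaned downward in G2. Of 388 tested lncRNA genes, 32 were higher and 66 lower in G2 than in UF, a balance that differed from that of the other called genes (Fisher's exact test, adjusted p = 0.000674 over 15 tests). In G5 vs UF 36 were higher and 48 lower (Fisher's exact test, adjusted p = 0.117), and in G5 vs G2 23 were higher and 7 lower (Fisher's exact test, adjusted p = 0.0103). The share of counts in lncRNA genes was 4.42% ± 0.0247 in UF, 0.953% ± 0.156 in G2 and 1.52% ± 0.175 in G5 (SD, n = 3, exact permutation p = 0.1 for each pair, two-sided). LOC8036515 accounted for this fall: without it the shares were 0.435% ± 0.0064, 0.489% ± 0.0024 and 0.616% ± 0.051, rising from UF to G5. As shares of TPM, lncRNA genes held 2.57% in UF, 2.70% in G2 and 3.30% in G5. Transcribed pseudogenes, of which 16 were tested, held 0.257% ± 0.0123 of counts in UF, 0.652% ± 0.0666 in G2 and 0.607% ± 0.055 in G5.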

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

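The tests of G2 replicate 2 and of the chance arrangement of genes, here and in the other parts, were chosen after the result was seen. With groups of 3 libraries no single library was tested as far from its group. The results set out here are genes that moved in opposite directions from UF in the fed groups, with the difference between G5 and G2 itself passing edgeR's test. All 100 genes called in opposite directions met that last condition, so it removed none and adds little to the calls against UF. There were 33 genes higher in G2 and lower in G5 than in UF, and 67 genes lower in G2 and higher in G5. LOC8024467 had the largest G5 vs G2 change of the 33, at 18 ± 7.02 CPM in UF, 81.6 ± 66.6 in G2 and 0.478 ± 0.225 in G5 (SD, n = 3), with 44 CPM in G2 without G2 replicate 3. LOC8042333 had the largest of the 67, with 9 counts in all of UF, none in G2 and 28.9 ± 15.6 CPM in G5 (edgeR adjusted p = 0.0416 for G2 vs UF and 6.19e-05 for G5 vs UF). At least a 2-fold change on both sides was seen in 18 of the 100 genes, 3 of them higher in G2. The 100 fell to 56, 54 and 52 without UF replicate 1, 2 or 3, and the cause was not tested. Leaving out 1 fed library gave 70 to 118.

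G2 replicate 2 lay closest to the unfed libraries, at 38.9 on the first principal component against 52.3 and 65 for the other G2 libraries. Unfed gland RNA mixed into it would bring genes that are off in the other G2 libraries at the share seen for all fallen genes. The 296 genes at least 4-fold lower in the other G2 libraries than in UF stood a median of 4.77% of the way to UF (bootstrap 95% interval 3.42 to 6.15), but the 7 genes off in both other libraries stood at 0.11% (0 to 0.17), which argues against mixing. These 7 include LOC120841911 and LOC120841921, whose reads RSEM had split with other genes. The bootstrap takes the genes as independent, so the interval of the 7 may be too narrow. Whether the pool was at an earlier stage of the same change cannot be told apart from other sources of its position: 86.7% of 481 risen genes were lower and 74.7% of fallen genes were higher in G2 replicate 2, but a library nearest UF on that component shows this by construction. One of 3 libraries always lies closest, and the labels give the same mean weight for each G2 pool.

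Replicates of the fed groups spread more than those of UF, with a dispersion 2.61 times that of UF in G2 and 2.45 times in G5. A difference in depth is argued against, since the ratios were 2.83 and 2.7 after thinning all libraries to 1 total. A single odd library is also argued against, since the least variable pair of G2 libraries still stood at 2.09 times UF and that of G5 at 2.16. Fewer females per pool could account for it, as the ratios 2.61 and 2.45 stay under the pool size ratios of 3 and 3.75. Over pairs of libraries the ratios ran from 1.74 to 4.35 in G2, past its pool size ratio, and from 1.8 to 3.6 in G5. G5 pools held fewer females than G2 pools but did not spread more. Pool size follows the feeding group, so a wider range of feeding states among fed ticks remains equally open and untested.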

How the results depend on the processing

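The limma-voom fit, the fit of only genes with whole expected counts and the changed lncRNA shares were chosen after the data were seen. Of 272 alternative values of 13 counts of genes, 256 lay within 1.5 times the value reported. Restricting the test to the 7311 genes with whole counts gave 3845 genes in G2 vs UF (2624 at least 2-fold), 4235 in G5 vs UF (3115), 1843 in G5 vs G2 (877) and 4748 over the 3 groups. It gave 3030 genes called in both fed groups in the same direction and 61 in opposite directions, 2717 called at the first step only, and 517 in the same and 611 in opposite directions at both steps. Fewer genes tested explains these lower counts. Leaving out 1 library gave 5254 to 6141, 5747 to 6658 and 2075 to 2875 genes for G2 vs UF, G5 vs UF and G5 vs G2, 52 to 118 for opposite directions from UF, and 634 to 1226 for opposite directions at both steps; the cause of the last 2 was not tested. Of 1265 alternative values for genes of the naming rule, 1245 kept their direction and side of the threshold, 10 lost their call, 10 gained one and none reversed. Same-numbered libraries did not deviate together (correlations -0.04 to 0, against -0.06 to 0.06 for different numbers). The labels do not say that a number marks a shared rabbit or day, and a modest shared effect is not excluded. A fit with a replicate block called 5825, 6254 and 2557 genes.

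In 1 of the 10 splits of the 6 libraries, the real one, as many genes were called as reported: 6056 for G2 vs UF (highest other split 0), 6503 for G5 vs UF (0) and 2829 for G5 vs G2 (1). With 10 splits the share cannot fall under 0.05. For the test over 3 groups only 1 of 100 drawn splits, the real one with 7360 genes, reached that number. The highest other split gave 4669. This argues against a random division of the libraries, at the smallest share that 100 draws allow. It does not test effects of pool or host that follow the groups. The planned gene list tests, secreted family shares and family counts were not run for want of product names. Thinning to the shallowest library gave 6055, 6485 and 2821 genes, so differences in depth between libraries had little effect, while genes at a few counts remain limited by depth.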

Other observations

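The tests of gene length, of runs of genes, of the share per sequence and of chance arrangement were chosen after the data were seen; those of split reads and gene models among neighbours were set before their results. Genes called with at least an 8-fold change were shorter than uncalled genes. Called genes with smaller changes were not compared. The median effective length of the 706 genes at least 8-fold higher in G2 than in UF, of those with a length, was 922.5 bases against 1703 among 5628 uncalled genes (permutation p = 1e-04, the smallest these permutations can give; adjusted p = 3e-04 over 6 tests). For the genes at least 8-fold higher in G5 than in UF it was 1122 bases (permutation adjusted p = 3e-04), and for those at least 8-fold lower 1403 bases (permutation adjusted p = 0.00204). The difference was smallest for genes at least 8-fold lower in G2 than in UF, at 1482 bases (permutation adjusted p = 0.0091). In G5 vs G2 the medians were 1327 bases for higher and 732.5 for lower genes, against 1768 (permutation adjusted p = 0.00075 and 4e-04). Under 1000 bases were 54.1% of the genes 8-fold higher in G2, against 25.2% of uncalled genes. A fractional count in some library was found in 39.2% of the genes at least 8-fold higher and 52.7% of those at least 8-fold lower in G2 than in UF, against 40.8% of uncalled genes. In G5 vs UF it was found in 37.3% of the higher and 41.4% of the lower genes, against 43.4%, and in G5 vs G2 in 45.7% and 47.4%, against 40.2%. An effective length was known for at least 93.3% of each set.

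A small part of the strongly changed genes lay in runs of neighbours, in the comparisons with UF more than in shuffled positions. In G2 vs UF there were 27 runs of at least 4 adjacent tested genes that all changed at least 4-fold in 1 direction, holding 148 of the 1940 genes that changed that much, against a mean of 1.08 and at most 6 runs in 1000 shuffles of gene positions. In G5 vs UF there were 30 runs with 159 of 2311 such genes, against at most 9 runs in the shuffles. In G5 vs G2 there were 2 runs with 8 of 576, against at most 1. The longest G5 vs G2 run held 4 genes and the longest in its shuffles 5, so that comparison passed its shuffles barely in number and not in length. The longest run, 14 tested genes from LOC8035806 to LOC120840184 (74567916 to 75529839), rose in both fed groups from a summed 0.389 CPM in UF to 886 in G2 and 842 in G5, and 10 of its genes had no count in UF. None of its 14 genes had whole counts in all 9 libraries, so RSEM divided reads among genes there and the levels of single members are uncertain. A run of 12 genes in G5 vs UF, from LOC8041436 to LOC115311997 (119721771 to 121254747), rose from a summed 6.24 CPM in UF to 918 in G5. Its sum was highest in G2, at 1400 CPM, and 9 of its 12 genes had whole counts. The longest falling run in G2, 10 genes from LOC8043999 to LOC121835372 (40495601 to 40592879), went from a summed 1460 CPM in UF to 82.4 in G2 and 140 in G5, and none of its 10 genes had whole counts in all 9 libraries either. On the stretch that holds LOC120841911, 72.7% of tested genes were at least 4-fold lower in G5 than in UF, against 22.2% in the next highest of 45 sequences with at least 6 tested genes and at most 66.7% for any sequence in 1000 shuffles. These shares rest on inferred boundaries between sequences, of which some can be missed. The shuffles also take genes as independent, while RSEM had split reads of most of the fallen genes on that stretch with other genes. A single fall may therefore be counted in several of them.

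Over all tested genes, those in runs included, adjacent genes had a Spearman correlation across gene pairs of 0.122 for the G5 vs UF log2 fold changes. A chance arrangement is argued against, since the highest of 1000 shuffles was 0.031. Reads split between near-identical copies do not account for all of it, since genes with whole counts gave 0.095 (highest shuffle 0.034). Overlapping gene models do not either, since adjacent genes at least 50 kb apart gave 0.085 (highest shuffle 0.058). That distance does not exclude fragments of 1 gene, since a single gene such as LOC8026527 spans 124169 bases. The limits on whole counts and on distance were not applied together, so split reads and fragmented models acting jointly are not excluded. The G5 vs G2 correlation at that distance, 0.056, barely passed its highest shuffle of 0.054. A candidate explanation is that neighbouring genes, such as members of duplicated families, are switched together during feeding; with no product names or sequences used here, family membership was not tested.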
